A study of Canis lupus familiaris with 13 samples.

How the data were processed

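RNA from 13 primary soft tissue sarcomas of dogs was compared between 5 tumours of the metastatic group and 8 of the non-metastatic group. Per the labels' protocols, total RNA of untreated tumours was purified on silica columns, labelled with biotin by 1 cycle of 3′ in vitro transcription and hybridised to an Affymetrix canine array, on which each transcript is read by a set of short probes (a probe set). The authors deposited 1 table of processed values for all arrays, and its values were read as log2 intensities. The scale was inferred from the values, which run from 0 to 14.33, and the software, background correction and normalization method are not given in the sources used here. Sample medians lay between 6.71 and 6.94, and the distributions were not identical. The values were used as deposited, since medians and quartiles differed by less than the limit set for renormalizing. A total of 105 values in 71 probe sets were exactly 0 and were kept. The number of arrays limits the precision, and no detection calls were used here.

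The table held 43035 probe sets, of which 111 Affymetrix controls were left out of the tests, leaving 42924, 64 of them reporter probe sets. Gene names came from the platform annotation supplied with the data. It gave 1 gene symbol for 29264 probe sets, several for 439 and none for 13332, and the named ones covered 15156 genes. The gene identifiers of 27690 named probe sets were found in the RefSeq gene table of assembly UU_Cfam_GSD_1.0, and 0 symbols changed through it. Probe sets with several symbols were not named, and no coordinates are given because the annotation of the array carries none. Some probe sets can bind transcripts of related genes, so each named gene is described by 1 probe set, together with its other probe sets where these differ in sign or in passing.

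Groups were taken from the sample labels. Differences are metastatic minus non-metastatic on the log2 scale. Each probe set was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 42924 probe sets and a threshold of 0.05. Errors of differences are standard errors (SE) from that fit, and errors of group means are standard deviations (SD). A gene list was scored in each sample as the mean of its members' log2 values after centring each gene, with each gene represented by its probe set of highest mean. List differences were tested by an exact two-sided permutation test over all 1287 splits of the samples, adjusted over the 27 lists with at least 5 measured genes. A further list of Y-linked genes had 0 measured members and was not analysed here. Group separation was the mean Pearson correlation within groups minus that between groups over the 5000 most variable probe sets, with an exact one-sided permutation test. The spread within groups was the mean of 1 minus the correlation, compared by an exact two-sided permutation test. Permutation tests and principal components used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

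The lists, the tests, their main settings and the rule for naming genes were set before the data were examined. The rule named the 12 higher and 12 lower genes with the largest differences past the threshold, taking each gene at its probe set of smallest p, up to 4 members of each list with the smallest p at the probe set chosen for the list, and several genes fixed by name whatever their values. Other genes are named only where a count of few members needed it, or where it is said that they were chosen after their values were seen.

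Poly-A spike-in controls, bacterial transcripts added to RNA before labelling, were read from the control probe sets after the data had been seen. Their 3′ probe sets averaged above the threshold of 6 in 10 samples and between 4.25 and 4.66 in 3. Samples were therefore placed in labelling batch A (all 5 metastatic samples and non-metastatic replicates 5 to 8), batch B (non-metastatic replicates 1, 3 and 4, without spike-in signal) and batch C (non-metastatic replicate 2). In that last sample the spike-in signal at the 3′ end exceeded that at the 5′ end by 3.90, against at most 0.865 in the other samples. Only batch A held both groups, so comparisons were repeated within it, with 126 splits for permutation tests. Smaller batches inside batch A cannot be excluded. The spike-in probe sets of samples without spike-in had a median of 4.14 and a range of 2.63 to 7.16, which is the size of value that these probe sets gave without their target. The upper end of 7.16 is their single highest value and lay above every sample median (6.71 to 6.94). A value not above it is therefore not shown to lack signal, and is only not told apart from that range.

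The fit was tested on simulated data before use, with 200 probe sets changed among 42924. The noise was normal and independent between probe sets, without labelling batches. The shares below therefore do not cover correlated probe sets or batch differences. For the comparison of all samples, 58% of changes of 1 on the log2 scale and 93.5% of changes of 2 were recovered, with 10 and 9 other calls. Within batch A the shares were 58% and 90%. For lists over all samples, the permutation test gave p under the threshold in 5.7% of 1000 simulated lists without a shift and 88.6% with a shift of 2 SD.

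Alternatives covered leaving out each sample in turn, the replicate number as a block, filters on low mean or low variance, quantile normalization, a trended robust prior, array weights, a threshold of 0.1, 1 probe set per gene, camera with a preset correlation of 0.01 or an estimated one, other scorings of the lists, and other choices of probe sets and correlation for the structure of the samples. Added after the data had been seen were the labelling batch as a block, batch A alone, all samples without batch B, the first principal component of the residuals as a covariate, and the 3′ minus 5′ value of the ACTB control, a measure of RNA degradation, as a covariate. The planned surrogate-variable alternative was not run. Pseudocounts did not apply, because the values were already on a log scale.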

Results

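Transcript levels were measured in biopsies of 13 untreated primary soft tissue sarcomas of dogs, a family of malignant tumours of connective tissue, on an Affymetrix canine array. The metastatic group held 5 tumours, and the non-metastatic group held 8 tumours without metastasis over at least 1 year. The comparison addressed which transcripts differ between primary tumours of these outcomes. Median log2 intensities lay between 6.71 and 6.94 in the 13 samples. The labels do not say whether the tumours came from separate dogs, so the p-values measure the spread between these samples. All 5 metastatic samples and 4 of the non-metastatic samples were in labelling batch A, 3 non-metastatic samples were in batch B and 1 was in batch C, as read from spike-in controls. The 3′ minus 5′ value of the ACTB control, which rises with RNA degradation, averaged 1.96 ± 0.59 (SD, n = 5) in metastatic and 1.47 ± 0.92 (n = 8) in non-metastatic samples. The difference was not past the threshold over all samples (exact permutation p = 0.316) or within batch A (exact permutation p = 0.460).

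Tumours of one outcome resembled each other more than tumours of the other. Over the 5000 most variable probe sets the mean correlation was 0.834 within groups and 0.733 between groups, a separation of 0.102 (one-sided exact permutation p = 0.000777, the smallest these splits can give). Within batch A the separation was 0.0789 (exact permutation p = 0.00794, also the smallest possible). The first principal component held 36.8% of the variance and placed the metastatic samples between -57.35 and -42.06. Of the non-metastatic samples, 7 lay between 18.15 and 68.12, and replicate 2, the single sample of batch C, lay at -31.67. Batch B lay farther out on this component than the non-metastatic samples of batch A, and 9311 probe sets differed between these non-metastatic samples of batches A and B (limma). The mean distance between samples was 0.194 among metastatic and 0.156 among non-metastatic tumours, a difference of 0.0383 that was not past the threshold (exact permutation p = 0.389). Within batch A these distances were 0.194 and 0.104, and the difference of 0.0902 had an exact permutation p of 0.0476. Both tests exchange samples between groups that also differ in level, so their p does not measure a difference in spread alone.

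**Figure D1:**
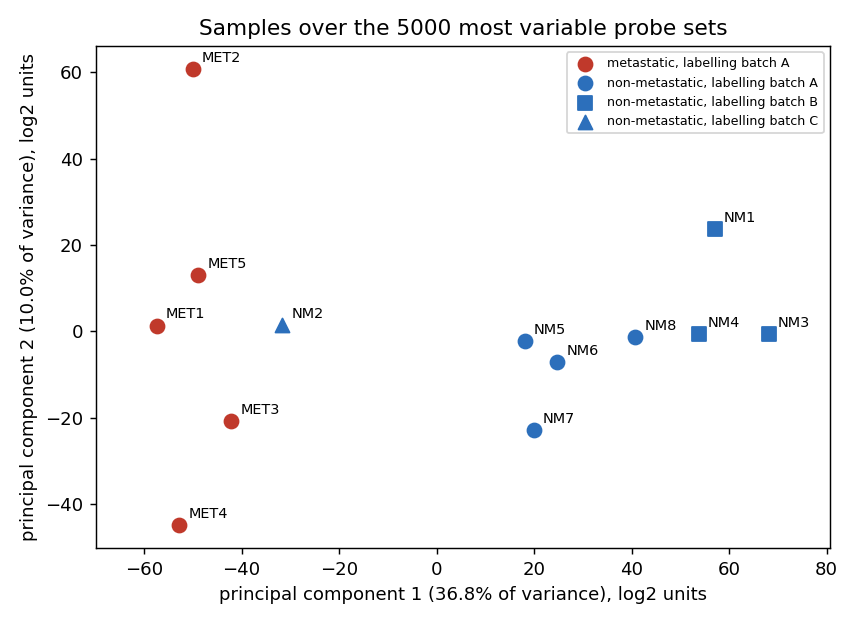
Position of the 13 samples on the first 2 principal components of the 5000 most variable probe sets, in log2 units, with colour for the disease group and shape for the labelling batch. The metastatic samples lie between -57.35 and -42.06 on component 1, beside non-metastatic replicate 2 at -31.67, and the other non-metastatic samples lie at 18.15 or above.

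The largest differences between the groups were falls in metastatic tumours. F2RL2, a protease-activated receptor, averaged 5.26 ± 1.14 (SD, n = 5) in metastatic and 10.82 ± 0.80 (n = 8) in non-metastatic tumours, so it fell by 5.56 ± 0.48 (SE, limma adjusted p = 0.000325). Its metastatic values, 4.13 to 7.12, lay inside the range of 2.63 to 7.16 of probe sets without target, so the size of the fall is not exact. CLEC3B, which encodes the plasminogen-binding protein tetranectin, fell by 4.88 ± 0.44 (SE, adjusted p = 0.000325), and KRT7, a keratin of simple epithelia, fell by 4.51 ± 0.46 (SE, adjusted p = 0.0005). Among the transcripts that rose, FHL2, a LIM-domain coactivator, was 3.74 ± 0.53 (SE) higher, at 9.28 ± 0.51 (SD, n = 5) against 5.54 ± 1.26 (n = 8), with a limma adjusted p of 0.00311. MYH10, a non-muscle myosin heavy chain, was 3.11 ± 0.40 (SE) higher and ETV1, a transcription factor of the ETS family, 3.05 ± 0.36 (SE) higher (adjusted p = 0.00201 and 0.00165).

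Among the 12 genes with the largest falls were also RFPL4B (-5.34), HHIP (-4.25), which binds and restrains hedgehog ligands, and the neuropeptide NPY (-4.00). The others were the lipid transporter ABCA8 (-3.91), the interleukin-13 decoy receptor IL13RA2 (-3.83), ITIH5 (-3.69), the ectonucleotidase ENTPD2 (-3.55), the ephrin receptor EPHA3 (-3.54) and the bone morphogenetic protein antagonist CHRDL1 (-3.34). All 12 also passed the test within batch A, where F2RL2 fell by 5.70, CLEC3B by 4.52 and KRT7 by 4.49. For 8 of the 12 every metastatic sample lay below every non-metastatic sample, the exceptions being HHIP, NPY, EPHA3 and CHRDL1. The largest rises were those of ANK3, a membrane-cytoskeleton adaptor (4.28 ± 0.83, SE), and NEFL, the neurofilament light chain (4.24 ± 1.09, SE). Both were uneven among metastatic tumours: NEFL ran from 9.54 to 10.94 in 3 of them and lay at 3.98 and 4.01 in the other 2, and ANK3 was 3.63 in replicate 2 and at least 7.52 in the others. The remaining rises were those of the proteoglycan GPC6 (3.50), the secreted Wnt antagonist SFRP1 (3.02), LOC607467 (2.80), the matrix protein TGFBI (2.60), the chromatin proteins HMGB3 (2.60) and HMGA1 (2.59), and the kinase anchor AKAP11 (2.52).

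Of the 12 named rises, FHL2, MYH10, ETV1, LOC607467, TGFBI and HMGB3 passed within batch A, with differences of 3.53, 2.97, 2.71, 3.04, 2.49 and 2.29. ANK3, NEFL, GPC6, SFRP1, HMGA1 and AKAP11 did not, at 4.59, 4.34, 3.06, 2.99, 2.33 and 3.02, with limma adjusted p from 0.0612 to 0.194, while 1 of the other 7 probe sets of ANK3 did (1.02, adjusted p = 0.0388). LOC607467 rests on 1 passing probe set of 14, of which 11 had the same sign, and the other probe set of AKAP11 had the opposite sign. NEFL and SFRP1 each lost their calls in 10 of the 13 fits without 1 sample, LOC607467 in 11, and AKAP11 and NPY in 7. The metastatic mean was not above 7.16, the highest value of probe sets without target, for 11 of the 12 falls (all but CLEC3B), with RFPL4B lowest at 2.67 ± 0.37 (SD, n = 5), nor was the non-metastatic mean for any of the 12 rises. The sizes of these differences are therefore not exact. Neither mean was above it for ETV1 and AKAP11, nor for KRT8, GAPDH, NF2, TP53INP1 and LSS below, 7 of the 58 named genes that passed.

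**Figure D2:**
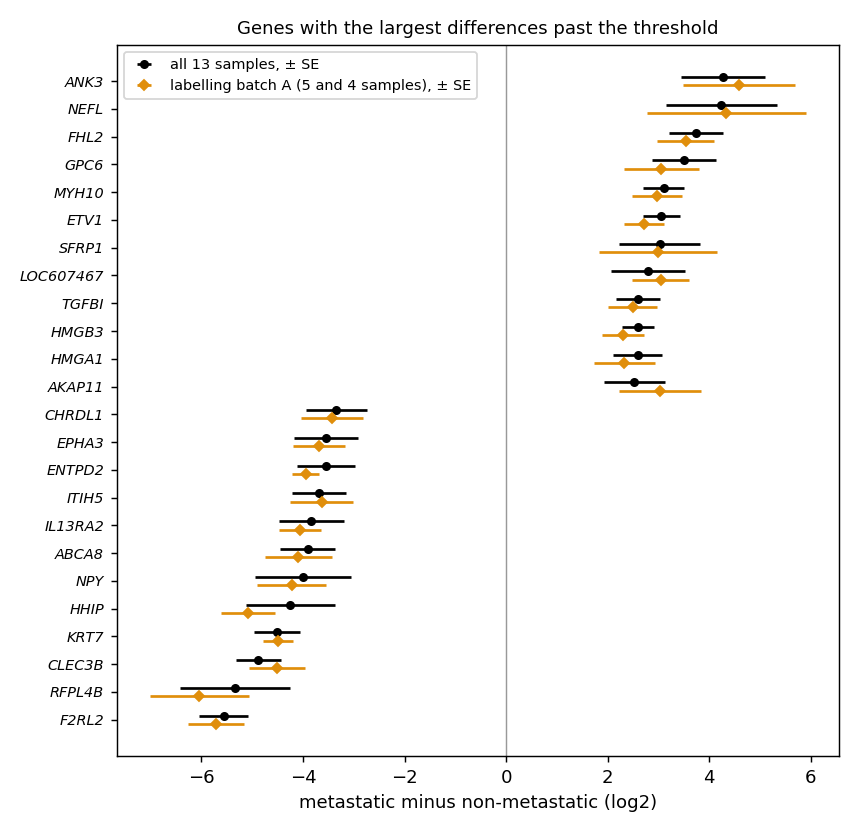
Difference between metastatic and non-metastatic tumours in log2 units, with its standard error, for the 12 genes with the largest rises and the 12 with the largest falls past the threshold, each at its probe set of smallest p, over all 13 samples (black) and within labelling batch A (orange, 5 and 4 samples). The 2 values of each gene have the same sign, from F2RL2 at -5.56 and -5.70 to ANK3 at 4.28 and 4.59.

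Over all probe sets, 2104 changed (limma, adjusted p under 0.05), 669 of them higher and 1435 lower in metastatic tumours, and 1131 changed by 1 or more on the log2 scale. They named 366 genes that were higher, 737 that were lower and 1 with probe sets in both directions, and 607 of them had no gene named. Within batch A 1192 probe sets changed, 248 higher and 944 lower, and without non-metastatic replicate 8 this count was 259, with 30 higher and 229 lower. Leaving out any other single sample of batch A gave 627 to 1207. Of the 1192, 831 were also called over all samples in the same direction and 0 in the opposite one, where both comparisons use the samples of batch A. With the labelling batch as a block the count was 1661, with 400 higher and 1261 lower. Batches B and C hold no metastatic sample, so the group difference in that fit is the one within batch A. Of the calls over all samples, 584 of 669 higher ones were also higher in non-metastatic samples of batch A than of batch B. Likewise 1052 of the 1435 lower ones were lower there, and all 2104 kept their sign within batch A. The counts moved with the samples used and with a covariate. Without batch B, which leaves batch A and non-metastatic replicate 2, 207 probe sets changed. With the ACTB 3′ minus 5′ value as a covariate the count was 1367 over all samples and 842 within batch A. Without non-metastatic replicate 2 there were 4478.

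Transcripts of cell division were higher together in metastatic tumours. CDK1, the kinase that drives entry into mitosis, rose by 2.02 ± 0.27 (SE), from 7.76 ± 0.54 (SD, n = 8) to 9.78 ± 0.47 (n = 5), with a limma adjusted p of 0.00262. TOP2A, which untangles replicated DNA, rose by 2.55 ± 0.41 (SE), the ribonucleotide reductase subunit RRM2 by 1.90 ± 0.30 (SE) and the spindle protein DLGAP5 by 1.88 ± 0.31 (SE), with adjusted p of 0.00529, 0.00444 and 0.00572. Of the 26 measured genes of the cell cycle and mitosis list, 18 rose and 0 fell over all genes, 23 rose when adjusted over the list alone, and all 26 had positive differences. The list score was 0.83 ± 0.52 (SD, n = 5) in metastatic and -0.52 ± 0.31 (n = 8) in non-metastatic tumours. The difference of 1.34 had an exact permutation p of 0.000777, the smallest possible, and an adjusted p of 0.021. In camera the adjusted p was 4.0e-18 with the preset correlation of 0.01 and 0.434 with an estimated one of 0.469. Every metastatic sample scored above every non-metastatic one. The DNA replication list differed by 0.51 (exact permutation p = 0.00155, adjusted p = 0.021), with an adjusted p = 0.686 with an estimated correlation. Of its 24 genes, 3 rose and 0 fell, and 13 rose when adjusted over the list alone. The 3 were GMNN, an inhibitor of origin licensing (1.39 ± 0.27, SE), FEN1, a flap endonuclease (1.00 ± 0.22, SE), and POLE2, a polymerase subunit (0.82 ± 0.21, SE). CDC6, which loads the replicative helicase, differed by 0.72 and did not pass at the probe set chosen for the list (limma adjusted p = 0.0537), while its other probe sets passed at 0.73 and 1.53 (adjusted p = 0.0333 and 0.0195).

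Genes of sterol and fatty acid synthesis were also higher. SQLE, the squalene epoxidase of cholesterol synthesis, rose by 2.46 ± 0.47 (SE), to 8.85 ± 1.20 (SD, n = 5) from 6.39 ± 0.70 (n = 8), with a limma adjusted p of 0.0117. The non-metastatic mean was not above the 7.16 of probe sets without target, so the size of the rise is not exact. SCD, the stearoyl-CoA desaturase, rose by 2.13 ± 0.44 (SE) and the sterol demethylase CYP51A1 by 0.83 ± 0.16 (SE), with adjusted p of 0.0177 and 0.0137. LSS, the lanosterol synthase, rose by 0.64 ± 0.17 (SE, limma adjusted p = 0.0433), with both group means not above 7.16. With FADS2, a fatty acid desaturase, these made 5 of the 20 measured genes of the cholesterol and fatty acid synthesis list, and 0 fell. Adjusted over the list alone, 9 rose and 1 fell. The list differed by 0.51 (exact permutation p = 0.00233, adjusted p = 0.021), with an adjusted p = 0.708 with an estimated correlation.

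Within batch A the differences of these 3 lists were 1.21 for the cell cycle, 0.45 for DNA replication and 0.51 for cholesterol and fatty acid synthesis, with exact permutation p of 0.0159, 0.0397 and 0.0238 and adjusted p of 0.214, 0.268 and 0.214. With 9 samples in place of 13, single genes past the threshold there were 7 of 26 of the cell cycle list, 0 of 24 of DNA replication and 2 of 20 of cholesterol and fatty acid synthesis. The median differences of all members were 1.31, 0.44 and 0.36, against 1.42, 0.49 and 0.35 over all samples. TOP2A, GMNN, FEN1, POLE2, CYP51A1 and LSS did not pass within batch A at their chosen probe sets, with differences of 2.06, 1.15, 0.84, 0.80, 0.76 and 0.46 and limma adjusted p of 0.0512, 0.0506, 0.137, 0.111, 0.0822 and 0.167, while the other probe set of TOP2A (2.10) and 1 of the other 2 of CYP51A1 (1.51) did. POLE2 lost its call in 10 of the 13 fits without 1 sample, LSS in 11 and FEN1 in 3. With 126 splits and 27 lists the smallest possible p becomes 0.214 there for a single list, and less only where other lists have small p as well. All 3 calls were also lost when metastatic replicate 1, 2, 4 or 5 was left out, where the smallest p of 495 splits, 0.00202, becomes 0.0545 for a single list.

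**Figure D3:**
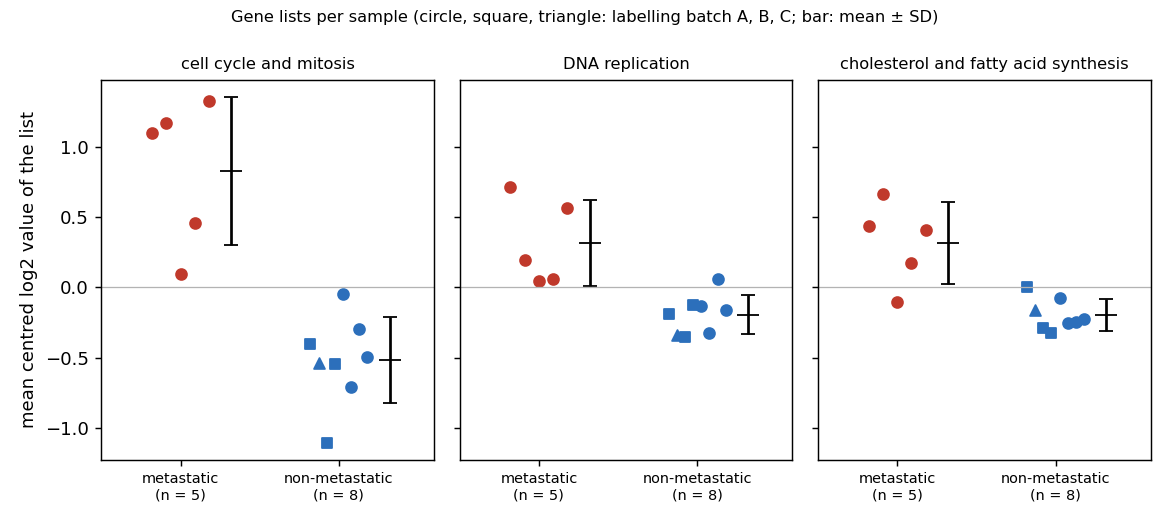
Score of each sample for the 3 gene lists past the threshold, as the mean centred log2 value of the list, with the mean and SD of each group and shapes for the labelling batch. The group means are 0.83 and -0.52 for the cell cycle, 0.31 and -0.20 for DNA replication and 0.31 and -0.20 for cholesterol and fatty acid synthesis.

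No list of matrix or motility genes passed the test, while single members differed. Decorin (DCN), a collagen-binding proteoglycan, fell by 1.29 ± 0.20 (SE), from 13.66 ± 0.11 (SD, n = 8) to 12.37 ± 0.58 (n = 5), with a limma adjusted p of 0.00429. It was the only one of 26 genes of the fibrillar collagen and extracellular matrix list to pass, also when adjusted over the list alone, and the list differed by 0.17 (adjusted p = 0.741) and by 0.32 within batch A. The DCN values of non-metastatic replicates 4 and 8 (13.72 and 13.73) were the highest on their arrays, so the size of its fall is not exact. COL6A1 and VCAN differed by -0.61 and -0.92 and did not pass. BGN differed by 1.29 and did not pass at its chosen probe set (adjusted p = 0.0917), while its other probe set passed at 1.39 (adjusted p = 0.0385) and within batch A (1.49). The gelatinase MMP2 fell by 1.39 ± 0.32 (SE, adjusted p = 0.0265) and its inhibitor TIMP2 by 1.00 ± 0.25 (SE, adjusted p = 0.038), 2 of 24 measured genes of the list of matrix proteases and inhibitors. Of the other 2 probe sets of MMP2, 1 also passed (-1.53) and 1 differed by 0.52 without passing. Within batch A neither gene passed (-1.23 and -0.79), and MMP2 lost its call in 4 and TIMP2 in 8 of the 13 fits without 1 sample. When adjusted over the list alone 2 rose and 4 fell. That list differed by -0.12 (adjusted p = 0.734) and by -0.11 within batch A. CTSK, a collagen-degrading cathepsin, differed by -0.87 without passing at its chosen probe set (adjusted p = 0.0591), while its other probe set passed at -1.05 (adjusted p = 0.0475). The sheddase ADAM10 (1.26) and the gelatinase MMP9 (-1.42 ± 0.64, SE, adjusted p = 0.20) did not pass. In the mesenchymal transition and motility list, the transcription factors TWIST1 and ZEB2 fell by 1.53 and 0.84 and the calcium-binding S100A4 by 1.70, with limma adjusted p of 0.0325, 0.0404 and 0.0353. Of these, TWIST1 also passed within batch A (-1.19), while ZEB2 and S100A4 did not (-0.48 and -1.46). In the 13 fits without 1 sample the calls were lost in 10 for TWIST1, 9 for ZEB2 and 7 for S100A4, and the metastatic mean of TWIST1 was not above 7.16. ZEB1 differed by 1.66 (adjusted p = 0.0526) and rose past the threshold within batch A (2.05, adjusted p = 0.024). All 5 probe sets of ZEB1 were positive, and 2 passed over all samples (1.85 and 1.44). TWIST1, ZEB2 and S100A4 were 3 of 28 genes over all genes, and 3 rose and 3 fell when adjusted over the list alone. The list differed by 0.13 (adjusted p = 0.552) and by 0.09 within batch A. EZR, which links membrane and actin, differed by -0.28 (adjusted p = 0.640).

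No list of immune or vascular markers passed the test. The macrophage and myeloid list differed by -0.08 (adjusted p = 0.989, -0.01 within batch A) and 0 of its 26 genes passed, with CSF1R at -0.49, CD163 at -0.72, MARCO at 0.41 and CSF2RB at 0.20. T cells and NK cells differed by 0.16 (exact permutation p = 0.0458, adjusted p = 0.248, 0.10 within batch A), and 0 of 25 genes passed, among them FOXP3 at 0.50, CD4 at 0.38, CD5 at 0.37 and IL2RB at 0.26. In the B cell and plasma cell list, differing by 0.16 (adjusted p = 0.481, 0.22 within batch A), SDC1, a proteoglycan also made by epithelial cells, rose by 0.57 ± 0.13 (SE, adjusted p = 0.0256), from a mean of 6.90 that was not above 7.16. It was 1 of 15 genes, 1 rose and 1 fell when adjusted over the list alone, and CD79A, POU2AF1 and FCRLA differed by -0.62, 0.67 and 0.26 without passing. With only genes at or above the median level this list differed by 0.32 and passed (adjusted p = 0.0135), while the whole list had an adjusted p = 0.984 with an estimated correlation in camera. The interferon list differed by 0.00 (adjusted p = 1, -0.11 within batch A) and antigen presentation by 0.20 (adjusted p = 0.741, 0.23 within batch A), with 0 of 23 and 0 of 22 genes past the threshold. IRF9 differed by -0.65, STAT2 by 0.22, DLA-DOB by 0.41 and PSMB8 by 0.56. The neutrophil and acute inflammation list differed by 0.03 (adjusted p = 1, 0.12 within batch A), and 2 of 22 genes passed. These were TNFAIP6, a hyaluronan-binding protein induced by inflammation, which fell by 2.37 ± 0.57 (SE, adjusted p = 0.0311), and NFKBIA, the inhibitor of NF-κB, which fell by 1.16 ± 0.30 (SE, adjusted p = 0.0394). The same 2 fell when adjusted over the list alone. Neither passed within batch A (-2.12 and -0.83, limma adjusted p = 0.122 and 0.0569), and they lost their calls in 8 and 9 of the 13 fits without 1 sample. Endothelial cells and angiogenesis differed by 0.20 (adjusted p = 0.741, 0.07 within batch A) with 0 of 24 genes passing. FLT1 differed by 0.75, ANGPT1 by 0.91 and VEGFA, the main endothelial growth factor, by -0.07 ± 0.44 (SE, adjusted p = 0.938) over all samples and -0.80 within batch A. Both group means of MARCO, FOXP3, CD4, CD79A, DLA-DOB, FLT1 and ANGPT1 were not above 7.16. For these genes the lack of a call therefore says little about a change of the transcript.

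Markers of other tissues that a biopsy can hold gave the following values. The keratinocyte and epithelium list differed by -0.34 (exact permutation p = 0.0187, adjusted p = 0.126) and by -0.34 within batch A, where its exact permutation p of 0.00794 was the smallest possible. Its members did not move together: 8 of 22 differences were positive and 14 negative over all samples (median -0.10), and 14 positive and 8 negative within batch A (median 0.06), where PPL (-2.71) and KRT8 (-4.33) had a large part in the mean. It passed after quantile normalization (-0.37, adjusted p = 0.0315) and without non-metastatic replicate 2 (-0.25, adjusted p = 0.0341), and had an adjusted p = 0.984 with an estimated correlation in camera. Of its 22 genes, periplakin (PPL), a desmosomal linker, fell by 2.68 ± 0.35 (SE, adjusted p = 0.00199) and KRT8, a keratin of simple epithelia, fell by 3.34 ± 0.89 (SE, adjusted p = 0.0468), and both fell when adjusted over the list alone. The KRT8 values, 0.66 to 2.28 in metastatic and 3.08 to 5.23 in 6 of 8 non-metastatic tumours, were not above the range of probe sets without target, and only non-metastatic replicates 7 (7.46) and 8 (8.84) exceeded it, so its fall is of uncertain size. It did not pass within batch A and lost its call in 10 of the 13 fits without 1 sample. DSG1 and PERP differed by -1.15 and 0.62 without passing. Skeletal muscle differed by 0.36 (adjusted p = 0.481, 0.24 within batch A), smooth muscle and pericytes by 0.25 (adjusted p = 0.595, 0.16 within batch A) and red blood cells and platelets by 0.10 (adjusted p = 0.741, 0.02 within batch A). In these lists 0 of 30, 0 of 24 and 0 of 8 genes passed, with ACTA1 at 1.41, MYLK at 1.63, ACTA2 at 1.14 and ALAS2 at -0.37. Both group means of DSG1 and ALAS2 were not above 7.16, so a change of their transcripts is uncertain. With a preset correlation camera also called skeletal muscle higher (adjusted p = 0.0174), but not with an estimated one (adjusted p = 0.984), and without metastatic replicate 5 the list differed by 0.11. The pericyte receptor PDGFRB differed by 0.64 ± 0.43 (SE, adjusted p = 0.367). Schwann cells and peripheral nerve differed by 0.02 (adjusted p = 1, -0.11 within batch A) with 0 of 17 genes passing, GAP43 at -2.62 and MPP6 at 1.70. GPM6B differed by -0.48 without passing at its chosen probe set, while another of its probe sets passed in the opposite direction (0.73, limma adjusted p = 0.0227). Within batch A that probe set did not pass (0.55). Adipocytes differed by 0.06 (adjusted p = 0.944, 0.03 within batch A). Here SCD rose and CFD, the complement factor adipsin, fell by 2.26 ± 0.45 (SE, adjusted p = 0.0144), 2 of 20 genes and the same 2 when adjusted over the list alone. Within batch A SCD passed (2.71) and CFD did not (-1.89).

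No signalling list passed the test, and single members changed. In the list of TGF-beta, Wnt and BMP signalling, TGFBI and SFRP1 rose, while the ligand TGFB2 fell by 2.54 ± 0.52 (SE, adjusted p = 0.0161), to a metastatic mean of 7.03 that was not above 7.16, its receptor TGFBR2 by 0.94 ± 0.21 (SE, adjusted p = 0.0249) and the BMP-induced regulator ID3 by 1.52 ± 0.35 (SE, adjusted p = 0.0271). These 5 of 29 genes also passed when adjusted over the list alone, and the list differed by 0.01 (adjusted p = 1, -0.08 within batch A). The immediate early list differed by -0.17 (adjusted p = 0.741, -0.12 within batch A), and 1 of its 27 genes passed: KLF4, a transcription factor of differentiation, fell by 2.90 ± 0.40 (SE, adjusted p = 0.0028), and 2 genes fell when adjusted over the list alone. FOSL2 and JUNB differed by -0.75 and -0.70. Among growth factor receptors and ligands, differing by 0.22 (adjusted p = 0.481, 0.06 within batch A), 1 of 27 genes passed, also over the list alone: the receptor FGFR2 fell by 3.32 ± 0.83 (SE, adjusted p = 0.036). PDGFB, PDGFA and FGF1 differed by 0.51, 0.44 and 1.13, and the receptor KIT by 0.05 ± 0.14 (SE, adjusted p = 0.829), without passing. Both group means of PDGFA were not above 7.16. Within batch A TGFB2, TGFBR2, ID3 and FGFR2 did not pass, at -2.21, -0.93, -1.75 and -3.51, while another probe set of FGFR2 did (-3.25, adjusted p = 0.044). TGFBR2, ID3 and FGFR2 lost their calls in 4, 5 and 10 of the 13 fits without 1 sample.

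No list of stress, energy metabolism or tumour suppressor genes passed the test. HERPUD1, which serves the degradation of misfolded proteins, fell by 1.33 ± 0.27 (SE, adjusted p = 0.017) and DNAJC3, a chaperone of the endoplasmic reticulum, by 0.77 ± 0.20 (SE, adjusted p = 0.046). They were 2 of 26 genes of the unfolded protein and heat shock list, 3 fell when adjusted over the list alone, and the list differed by -0.17 (adjusted p = 0.481, -0.25 within batch A). XBP1 and DNAJB1 differed by -0.59 and -0.76 without passing, while the other probe set of XBP1 passed at -0.62 (adjusted p = 0.0425). Of 23 genes of tumour suppressors and apoptosis, SESN1 and TP53INP1, both stress-induced, fell by 1.26 ± 0.34 (SE, adjusted p = 0.0463) and 0.59 ± 0.16 (SE, adjusted p = 0.0458), and NF2, the gene of merlin, rose by 0.66 ± 0.15 (SE, adjusted p = 0.0251). Adjusted over the list alone 4 rose and 4 fell, the list differed by -0.10 (adjusted p = 0.595, -0.18 within batch A), and 2 other probe sets of NF2 had the opposite sign. Hypoxia and glycolysis differed by 0.25 (adjusted p = 0.481, 0.07 within batch A). The probe set of the glycolytic enzyme GAPDH was higher by 0.51 ± 0.13 (SE, limma adjusted p = 0.0425). It was the only one of 31 genes to pass at the probe sets chosen for the list, and 0 passed when adjusted over the list alone. EGLN3 differed by 1.23 and ANGPTL4 by -0.89. P4HA2 differed by 1.598 without passing at its chosen probe set (limma adjusted p = 0.1004). Of its 6 probe sets, all positive, 2 passed, at 2.067 and 1.581 (adjusted p = 0.04146 and 0.04998). Neither of these passed within batch A (1.518 and 1.34). Both group means of GAPDH, NF2 and TP53INP1 were not above the 7.16 of probe sets without target, so a change of their transcripts is uncertain. Oxidative phosphorylation differed by 0.00 (adjusted p = 1, 0.08 within batch A) and ribosomal proteins by -0.13 (adjusted p = 0.481, -0.02 within batch A), with 0 of 25 and 0 of 21 genes passing. CYC1 differed by 0.78, ATP5F1C by -0.44 and RPS15 by -0.48. Within batch A HERPUD1 passed (-1.75), while DNAJC3, SESN1, TP53INP1, NF2 and GAPDH did not, at -0.57, -1.45, -0.64, 0.48 and 0.37, with limma adjusted p from 0.0547 to 0.198. Of other probe sets, 3 of SESN1 (-1.59, -1.52 and -1.50) and 1 of DNAJC3 (-1.07) passed there. These 5 lost their calls in 9, 10, 11, 3 and 9 of the 13 fits without 1 sample.

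Other probe sets of the genes named here did not always give the same result. Of genes without a passing probe set, at least 1 other probe set had the opposite sign for CSF2RB (2 of 3), STAT2 (3 of 5), CD163 (1 of 4), FCRLA (1 of 4), DSG1 (1 of 2), MMP9 (1 of 3), EZR (1 of 3) and DNAJB1 (1 of 4). Among called genes, all probe sets had the same sign but only some passed for ANK3 (6 of 8), RFPL4B and NPY (1 of 2 each), DLGAP5 (2 of 3), FEN1 (1 of 3), SCD and CYP51A1 (2 of 3 each), KLF4 (1 of 2), DNAJC3 (1 of 4), TGFBR2 (5 of 6) and SESN1 (4 of 5). Within batch A only some probe sets passed for MYH10, RFPL4B, NPY and KLF4 (1 of 2 each), DLGAP5, SCD and SQLE (1 of 3 each), ZEB1 (4 of 5) and LOC607467 (3 of 14). Of all 58 named genes that passed over all samples, 29 also passed within batch A at the same probe set. The other 29 had differences there of 58.0% to 129.6% of those over all samples (median 88.7%), all of the same sign, in a comparison with fewer samples. In the fits without 1 sample, 31 of the 58 kept their calls throughout.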

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

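The reading of the spike-in controls and the test of truncated labelling were chosen after the data had been seen, while both tests of a mislabelled sample were set before their results were seen. In 324 groups of samples, 54 for list scores and 270 for named genes, the highest or lowest sample was tested for standing apart from the rest, and 21 did (5 for lists, 16 for genes), against 16.2 expected by chance at 1 in 20. Non-metastatic replicate 2 accounted for 7 of them.

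In that sample the list score was 1.126 for neutrophils and acute inflammation (others -0.538 to 0.107), 0.44 for B cells and plasma cells (others up to 0.058) and 0.734 for keratinocytes and epithelium (others up to 0.288). Its log2 values were 10.69 for LOC607467 (other non-metastatic samples up to 7.89), 4.92 for ENTPD2 (others from 7.75), 7.87 for FGFR2 (others from 10.92) and 6.44 for EPB42 (others up to 5.95). The remaining 14 stood alone in a group without a common theme being tested. Metastatic replicate 5 had a skeletal muscle score of 1.25 (others up to 0.065) and an NPY value of 6.4 (others up to 4.71), and non-metastatic replicate 7 had a Schwann cell score of 0.47 (others up to 0.044). Metastatic replicate 2 had GAP43 at 11.7 (others up to 6.81), RBP4 at 6.3 (others from 11.54), RPS15 at 12.13 (others from 12.53) and DNAJB1 at 7.97 (others from 8.24). Metastatic replicate 3 had ETV1 at 8.14 (others up to 6.85), FEN1 at 8.21 (others from 9.11) and ATP5F1C at 10.68 (others from 10.98), and metastatic replicate 4 had ADAM10 at 12.33 (others up to 10.18). Non-metastatic replicate 4 had PROX1 at 5.06 (others from 5.98) and CYC1 at 8.0 (others from 8.88), and non-metastatic replicate 3 had FOXP3 at 3.31 (others from 4.14).

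Control probe sets left out of the comparisons also carried signal. The 3′ probe sets of the poly-A spike-ins averaged 8.467 in batch A and 8.43 in batch C, above the 4.25 to 4.66 of the samples of batch B.

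Non-metastatic replicate 2 lay at -31.67 on the first principal component, beside the metastatic samples. On the 1192 probe sets changed within batch A, which that sample had no part in choosing, its position was 0.745 (95% interval 0.716 to 0.774) on a scale from 0 for the non-metastatic to 1 for the metastatic mean, and on the 248 higher ones it was 0.605 (0.537 to 0.672), against 0.001, -0.148 and -0.047 over the 1192 for the samples of batch B. The intervals come from resampling the probe sets of 1 sample, so they do not measure the spread between tumours or labelling batches. These positions would go with a mislabelled sample, but the cell cycle score of that sample, -0.54, lay below the metastatic range of 0.10 to 1.32. Taken singly, 670 of the 944 lower probe sets (71.0%) and 141 of the 248 higher ones (56.9%) were nearer to the metastatic mean in that sample, and the others nearer to the non-metastatic mean. Truncated labelling of its RNA may contribute: its spike-in 3′ minus 5′ value was 3.898, and this cannot be told apart because batch C holds no other sample. A tumour of the non-metastatic group that resembles metastatic ones in part stays open and was not tested, and the label was kept.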

How the results depend on the processing

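The settings by labelling batch, ACTB control and residual component were chosen after the data had been seen. Group separation kept its direction and passed in all settings run, at 0.0886 to 0.128 without 1 sample, 0.263 and 0.0275 with 1000 or all probe sets, 0.128 with Spearman correlation and 0.0789 within batch A. All 2104 calls kept their sign in every setting with all 42924 probe sets and in the fits without 1 sample within batch A, all of which share samples with the main fit. The number of changed probe sets moved by under 1.5 times with quantile normalization (1942), the trended robust prior (2116), both filters (1951 and 2047) and the labelling batch as a block (1661). Without 1 sample the number ran from 856 to 4478 (higher 234 to 1731, lower 622 to 2747, by 1 or more on the log2 scale 591 to 1855). It moved by over 1.5 times without metastatic replicates 1 (856), 3 (1393) and 5 (982) and non-metastatic replicates 1 (1375), 2 (4478), 3 (1100), 4 (1105) and 8 (1218). Within batch A, leaving out 1 sample gave 259 (without non-metastatic replicate 8) to 1207. No detection calls were used, so genes near the background of the spike-in probe sets are limited in fold.

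Other counts are given as changed, higher and lower. The replicate numbers do not pair the samples (correlations of deviations 0.065, 0.078, 0.022, 0.038 and -0.009, and only the pair of number 2 correlated best with its own number). With the replicate block the counts were 733, 255 and 478, with 636 of 1 or more on the log2 scale. They were 4011, 1280 and 2731 with array weights, 4352, 1684 and 2668 at adjusted p under 0.1, and 7151, 3970 and 3181 with the residual component. With 1 probe set per gene they were 968, 317 and 651 (428 of 1 or more), where fewer were tested. The filter on mean level gave 431 higher and the labelling block 400 higher. Within batch A the counts were 1192, 248 and 944 (743), with the ACTB covariate 1367, 410 and 957 (721), with both 842, 147 and 695 (551), and without batch B 207, 46 and 161 (164). The set without batch B is batch A with non-metastatic replicate 2 added, and batch A alone, with fewer samples, gave 1192. Fewer samples therefore do not account for the 207. Some of the other settings have fewer samples or tests, and the cause of the other moves was not tested.

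The number of lists past the threshold was 3, and 0 with the replicate block, within batch A, without batch B and with an estimated correlation (all samples, and batch A). It ran from 0 to 4 without 1 sample. For the cell cycle, DNA replication and cholesterol lists the differences were 1.35, 0.54 and 0.48 with the replicate block (adjusted p = 0.422), 1.21, 0.45 and 0.51 within batch A, and 1.24, 0.49 and 0.50 without batch B (adjusted p = 0.107). Without 1 sample they ran from 1.22 to 1.53, 0.41 to 0.58 and 0.42 to 0.61, and all 3 calls were lost without metastatic replicates 1, 2, 4 or 5. In the block and the smaller sets the number of splits limits the adjusted p by construction. With the preset correlation camera called these lists over all samples (adjusted p = 4.0e-18, 1.6e-06 and 0.00091). It also called them within batch A (adjusted p = 1.7e-13, 5.1e-06 and 0.0018). The preset assumes a correlation of 0.01 between genes, where the estimates over all samples were 0.469, 0.269 and 0.2.

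The difference in spread turned to -0.00035 with all probe sets. Within batch A (0.0902) its permutation p was under the threshold, which does not measure spread alone because the groups also differ in level. Signs turned in 72 cases, 15 of genes and 56 of lists, none past the threshold on either side. The block turned the matrix (-0.039), neutrophil (-0.034) and VEGFA (0.59) values. Quantile normalization turned oxidative phosphorylation (0.18) and VEGFA (0.11), and scaling each gene turned tumour suppressors (0.043). The filter on mean level turned motility (-0.023), neutrophils (-0.19), Schwann cells (-0.11), adipocytes (-0.030) and TGF-beta (-0.23). Averaging probe sets turned interferon (-0.025), red blood cells (-0.039) and TGF-beta (-0.00069). Within batch A interferon (-0.11), Schwann cells (-0.11), oxidative phosphorylation (0.078), TGF-beta (-0.084) and TAPBP (-0.015, also with the labelling block) turned. Without batch B endothelium (-0.11), neutrophils (-0.12), interferon (-0.13), Schwann cells (-0.092), adipocytes (-0.042), red blood cells (-0.080), oxidative phosphorylation (0.065), TGF-beta (-0.14) and KIT (-0.004) turned. The ACTB covariate turned VEGFA (0.0039) and KIT (-0.0029, and -0.022 within batch A). Without 1 sample the ranges that crossed 0 were macrophages -0.29 to 0.13, neutrophils -0.086 to 0.19, interferon -0.18 to 0.22, antigen presentation -0.017 to 0.39, Schwann cells -0.038 to 0.091, adipocytes -0.083 to 0.17, oxidative phosphorylation -0.074 to 0.098, immediate early genes -0.27 to 0.013, TGF-beta -0.12 to 0.13, VEGFA -0.34 to 0.16 and KIT -0.051 to 0.099. The cause of these turns was not tested. The planned surrogate-variable and pseudocount alternatives were not run.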

Other observations

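The tests of the gene lists below, the splits of the samples, the labelling batches and the comparison for RNA degradation were all chosen after the differences had been seen. Beyond the lists fixed in advance, genes of differentiated fibroblasts were among those that fell most, chosen here because their values had been seen. The lipid transporters ABCA6 and ABCA9 fell by 3.18 ± 0.32 (SE, limma adjusted p = 0.000475) and 3.11 ± 0.79 (SE, adjusted p = 0.038), the matrix protein EFEMP1 fell by 2.88 ± 0.50 (SE, adjusted p = 0.00705) and ABI3BP by 3.38 ± 0.71 (SE, adjusted p = 0.0184), each at its probe set of highest mean. At its probe set of smallest p, which ranks the largest falls, ABI3BP fell by 3.28. With CLEC3B, ABCA8, CHRDL1, CFD and DCN these were the 9 of 23 list members picked because they had fallen, and 0 of the other 14 passed. The hedgehog effector GLI1 fell by 2.32 ± 0.40 (SE, adjusted p = 0.00679) and the co-receptor CDON by 1.21 ± 0.20 (SE, adjusted p = 0.00582), beside HHIP. The complement proteases C1R and C1S fell by 1.95 ± 0.33 (SE, adjusted p = 0.00611) and 1.66 ± 0.33 (SE, adjusted p = 0.015). In the other direction, the mitochondrial folate enzyme MTHFD2 rose by 1.48 ± 0.30 (SE, adjusted p = 0.0164) and the amino acid transporter SLC7A5 by 0.56 ± 0.10 (SE, adjusted p = 0.00988), while PHGDH, the first enzyme of serine synthesis, differed by 0.53 (adjusted p = 0.0561). The metastatic means of ABCA9 (6.27), GLI1 (6.51) and CDON (6.78), the non-metastatic mean of MTHFD2 (6.73) and both means of SLC7A5 (6.73 and 6.17) were not above the 7.16 of probe sets without target, so the sizes of these differences are not exact.

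Whether each of these 4 groups moved as a whole was tested on members that had not yet been looked at, since the genes above were picked for their differences. The picked genes held every measured member that passed over all samples, so the others lie nearer to 0 by selection. A general fall of differentiated fibroblast genes might be behind the first of them, but the other 14 members differed by -0.476 ± 0.344 (SE, exact permutation p = 0.152, adjusted over the 4 lists p = 0.305) and by -0.74 within batch A (exact permutation p = 0.0952). Of the 14, 10 differences were negative, with MFAP4 at -2.88 and PI16 at -2.36, and OGN was at 2.10. The abundant fibroblast transcripts COL1A1, COL1A2, COL3A1 and LUM differed by 0.43 ± 0.38 (SE, exact permutation p = 0.307) on average and by 0.54 within batch A, while all 23 list members together differed by -1.74 within batch A. These last tests were run as technical checks and decided nothing. The other 8 hedgehog members differed by -0.137 (exact permutation p = 0.269, adjusted p = 0.359), the other 10 complement members by 0.027 (exact permutation p = 0.935, adjusted p = 0.935) and the other 11 members of serine and one-carbon metabolism by 0.267 (exact permutation p = 0.101, adjusted p = 0.305). Within batch A these were -0.22, -0.02 and 0.07. Of these members 4 hedgehog, 5 complement and 9 serine and one-carbon differences were positive and 4, 5 and 2 negative. A change of a whole list by at least the smallest change of its picked genes was tested after all values had been seen. The need for the same result within batch A was added after a first run over all samples, where the fibroblast list also fell short. The test used the other members with a group mean above 7.16. For complement the 8 such members differed by -0.03 ± 0.39 (SE) and by -0.08 ± 0.35 (SE) within batch A. Both were short of the -1.66 of C1S by over 2 SE, so these 8 did not fall by that size on average. As the members that passed had been picked out beforehand, this cannot decide on a fall of the whole list. For fibroblast genes the 14 members, all above that level, differed by -0.476. This was short of the -1.28 of DCN by over 2 SE over all samples but not within batch A (-0.74 ± 0.35, SE). The size of the DCN fall is not exact, as its values in non-metastatic replicates 4 and 8 were the highest on their arrays. For hedgehog the 4 members differed by -0.317 ± 0.184 (SE) and by -0.489 ± 0.212 (SE) within batch A. Both were short of the -1.21 of CDON by over 2 SE, but the members were too few under the rule of the test. For serine and one-carbon metabolism the 9 members (0.219 ± 0.156, SE) were not short of 0.53 by over 2 SE over all samples. Within batch A they were (0.041 ± 0.168, SE). A change of that size, or a smaller one, stays open for each of the 4 lists.

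The number of changed probe sets was set against other explanations. Chance is an unlikely cause for the comparison of all samples. Of 100 splits into 5 and 8, drawn from all 1287 with the real one among them, 1 gave the real 2104 or more, namely the real split. This drawing can show a share no smaller than 1 in 100. The highest other split gave 484. That other split parted metastatic replicate 5 and non-metastatic replicates 1 to 4, which include all of batches B and C, from the rest. Within batch A chance is unlikely as well: 1 of 100 splits, the real one, reached 1192 and the highest other gave 108. The labelling batches alone are therefore unlikely to be the whole cause. The 1192 depend on single samples, with 259 left without non-metastatic replicate 8. With the ACTB control value as a covariate, 842 probe sets changed within batch A. The other splits drawn, fitted with the same covariate, gave at most 675. The split with 675 was the real one but for metastatic replicate 2, placed with the non-metastatic samples. The split that so places metastatic replicate 5 was not drawn. RNA degradation as read from that control is argued against as the whole cause only as far as the drawn splits go, and it is not excluded. Smaller batches inside batch A and tumour type, for which the labels give no value, stay open.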
